A study of Mus musculus with 4 samples.

How the data were processed

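Gene-level RNA-seq counts were analysed from 4 bone marrow libraries labelled as Lsk cells, 2 labelled Ppm1bfl/fl and 2 labelled Ppm1bCKO. Per the labels' protocols, total RNA was extracted from pre-sorted cells with TRIzol and libraries were made with a TruSeq RNA kit. The deposited table held raw whole-number counts per gene for the 4 libraries, not normalised. Per the submitters' processing notes, the tools included Trim Galore 0.6.7, HISAT2 2.2.0 and featureCounts 2.0.1, and the genome build was mm10. The annotation release, the strand setting and the treatment of reads that match several places were not given in the sources used here. Values of paralogs such as Oas1a and Oas1g, of immunoglobulin segments and of overlapping or antisense genes are therefore uncertain. A gene-level count sums reads over every exon, so the deletion of a few exons need not lower it.

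The table listed 55399 genes by Ensembl identifier, of which 55139 matched a GENCODE annotation of the same mouse build that gave symbols, coordinates and exonic lengths, and 260 did not. Where identifiers shared a symbol, the most abundant kept it, and the 107 rarer ones were named by identifier. The 37 mitochondrial genes were listed with 0 reads in all 4 libraries. No column of the table was left out. Total counts were 26002277 and 30045382 in Ppm1bfl/fl replicates 1 and 2, and 22393973 and 24856083 in Ppm1bCKO replicates 1 and 2. At these depths a count of 0 allows up to 3 counts, or 0.0998 to 0.134 CPM. Wilson intervals (95%) of shares of counts and these limits cover counting error only, because reads without molecular identifiers are not independent molecules.

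Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr by group with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood fit and test). The 2 genotypes were compared without covariates. P-values were adjusted by the Benjamini-Hochberg method over 16393 tested genes, with a threshold of 0.05. In the text "edgeR adjusted p" stands for this test. CPM values are TMM-normalised, fold changes are Ppm1bCKO over Ppm1bfl/fl, and errors of log2 fold changes are standard errors. Standard errors of list medians are taken over the genes of a list and leave out the spread between libraries. The biological coefficient of variation was 19.1%. Replicates of a genotype differed beyond sampling noise, with a chi-square per degree of freedom of 16.5 for the Ppm1bfl/fl pair and 33.6 for the Ppm1bCKO pair, so neither pair was taken for a single library deposited again. This does not show that the samples are independent.

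Before the data were examined, 27 gene lists were written for Wnt signalling, stem and progenitor programmes, cell cycle, stress and inflammatory pathways, metabolism, PPM phosphatases and the other cell types a bone marrow sort can hold. They were tested with camera (limma 3.58.1, inter-gene correlation preset at 0.01) and adjusted over the 27 lists, beside camera with an estimated correlation and the directional fry test. Members past the threshold were counted over all genes and adjusted over the list alone. Sex-linked genes were described but not tested as a list. Genes within 5 Mb of Ppm1b were compared with the rest of the genome by a two-sided Fisher's exact test, because a targeted allele can carry linked sequence. A further 4 lists (plasma cell genes other than immunoglobulin, B-lineage genes, plasmacytoid dendritic cell genes other than interferon-induced, and eosinophil granule genes) were written after the data were seen.

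The rule for named genes was also set before the data were examined. Ppm1b came first. Next came up to 12 genes per direction with the largest fold change among those past the threshold, with both libraries of a genotype on one side of both others and an average log2 CPM of at least 1. Predicted genes, clones and immunoglobulin or T cell receptor segments were left out. Where under 6 passed in a direction, genes with the smallest p filled the places up to 6 and were said not to have passed. Up to 4 members of each list with the smallest p could be named, and 17 genes, among them Ctnnb1, Axin2, Lef1, Myc, Procr and Ppm1a, whatever their p. Other genes named were chosen after their values were seen and are identified as such.

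The alternatives were DESeq2 size factors in the edgeR test, DESeq2 1.42.0, limma-voom, no low-count filter, a CPM of at least 1 in 2 samples, a minimum absolute log2 fold change of 1, the replicate number as a block, each library left out in turn, and windows of 1 and 10 Mb around Ppm1b. Removing each library's trend with gene length (lowess span 0.3) and leaving out immunoglobulin genes were added after the data were seen. The fit was tested on simulated counts of 15994 genes at the depths of this comparison, where 200 genes were changed. It recovered 40 of 100 genes changed 2-fold and 95 of 100 changed 4-fold, with 14 false calls. In a simulation with 27 lists, the 1 shifted list was called and 0 others were. Its genes were drawn independently, whereas the estimated correlation within a real list reached 0.83. It therefore does not give the rate of false list calls in these data.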

Results

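The expression of genes was measured by bulk RNA-seq in mouse bone marrow cells labelled Lsk. That name is usually given to the lineage-negative, Sca-1-positive, Kit-positive fraction that holds haematopoietic stem cells (HSCs) and multipotent progenitors. Of the 4 libraries, 2 were labelled Ppm1bfl/fl (alleles flanked by loxP sites) and 2 were labelled Ppm1bCKO (conditional knockout). The Cre line was not given in the sources used here. The series title names Ppm1b, a metal-dependent serine/threonine phosphatase, together with HSC self-renewal and the Wnt/β-catenin pathway, so the comparison asks which transcripts differ with the Ppm1b genotype. Total counts ran from 22393973 to 30045382 per library. The labels did not say whether replicates came from separate mice, so p-values measure only the spread between these libraries. Between the Ppm1bfl/fl libraries it may be technical, whereas the Ppm1bCKO libraries, with 5870 and 2 counts of Y-linked genes, did not come from a single mouse.

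Ppm1b transcripts were not lower in the libraries labelled Ppm1bCKO. Ppm1b (ENSMUSG00000061130.13, chromosome 17, 84956741 to 85023991, mm10) stood at 80.7 and 82.5 CPM in the Ppm1bfl/fl libraries and at 84.3 and 121 CPM in the libraries labelled Ppm1bCKO. Its log2 fold change was 0.33 ± 0.20 (edgeR adjusted p = 0.717) and ranged from 0.046 to 0.56 over the alternatives. The highest value came without Ppm1bCKO replicate 1, where replicate 2, which stood apart from the other libraries, alone represents the genotype. These counts sum reads over all exons and do not show whether an exon was deleted, so each direction given here rests on the labels alone. The related phosphatase gene Ppm1a had a log2 fold change of 0.01 ± 0.16. Among the 17 tested genes of the PPM phosphatase list, 0 changed over all genes or when adjusted over the list alone (camera adjusted p = 0.537, median log2 fold change -0.05).

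The libraries labelled Ppm1bCKO held fewer immunoglobulin transcripts and more transcripts of interferon-stimulated genes than the Ppm1bfl/fl libraries. Of 16393 tested genes, 61 changed, 10 higher and 51 lower, and 49 of the 51 were immunoglobulin genes. Variable and constant immunoglobulin entries can be parts of the same transcripts, so the 49 are not independent changes. The interferon-regulated genes Irf7, Oas1a, Oasl2, Ifit1 and Ifi27l2a rose by 2.33-fold to 3.30-fold. Components and targets of Wnt signalling included 0 changed genes, but only 12 genes outside the immunoglobulin family changed at all. Camera called the components lower as a list at the preset correlation, and not at an estimated one. The libraries of the genotypes did not overlap for any of the 61 genes, which their selection on the same libraries favours. Over all tested genes 41.1% did not overlap, where 33.3% are expected by chance. At an unadjusted p under 0.05 there were 1056 genes, where 820 are expected by chance. When immunoglobulin genes were left out of the fit, an alternative chosen after the data were seen, edgeR called 0 of 16177 genes, with 989 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 79. The other 12 calls kept their sign there, at edgeR adjusted p from 0.133 to 0.156, and DESeq2 called all 12.

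Interferon-stimulated genes were the list with the most changed members. Of its 42 tested members, 39 had a positive log2 fold change, 7 rose over all genes and 18 when adjusted over the list alone, and the median log2 fold change was 0.59 (camera adjusted p = 5.1e-29; adjusted p = 0.308 with an estimated correlation). Irf7, a transcription factor that amplifies type I interferon production, rose from 44.6 ± 0.7 to 104 ± 0.96 CPM (SD, n = 2), a log2 fold change of 1.22 ± 0.16 (edgeR adjusted p = 0.0204). Oas1a and Oasl2, of the oligoadenylate synthetase family that senses double-stranded RNA, rose by 1.35 ± 0.19 and 1.40 ± 0.20 on the log2 scale (edgeR adjusted p = 0.0274 and 0.0339). Ifi27l2a rose from 28.4 ± 3.5 to 93.8 ± 31.5 CPM (SD, n = 2; edgeR adjusted p = 0.0339). Ifit1, which binds foreign RNA caps, rose by 1.58 ± 0.23 and Ifi44 by 2.07 ± 0.30 on the log2 scale (edgeR adjusted p = 0.0365 and 0.0379). Usp18, a protease that removes ISG15 from proteins, rose by 2.77-fold (edgeR adjusted p = 0.0442). Oas1g and Rtp4, outside the list, rose by 5.10-fold and 2.53-fold (edgeR adjusted p = 0.0179 and 0.0461). Oas1a and Oas1g lie next to each other on chromosome 5 and are near-identical paralogs, so the split of reads between them is uncertain. Bst2, a member of both this list and the dendritic cell list, had a log2 fold change of 0.99 ± 0.25. The list median was close in both libraries labelled Ppm1bCKO, 0.53 in replicate 1 and 0.55 in replicate 2. The call of Irf7 was lost without Ppm1bfl/fl replicate 1 (1.20, edgeR adjusted p = 0.0715), and that of Rtp4 without Ppm1bfl/fl replicate 2 (1.20, edgeR adjusted p = 0.0909) and with a minimum of 1 CPM (1.34, edgeR adjusted p = 0.0548). Usp18 was not called by limma-voom (1.46, adjusted p = 0.0512). The remaining gene that rose, Lrrc10b, chosen after its values were seen because it fell below the abundance minimum for naming, went from 0.21 to 2.48 CPM, and its call was lost without Ppm1bCKO replicate 2 (2.96, edgeR adjusted p = 0.0812), with the CPM minimum (3.52, edgeR adjusted p = 0.0582) and by limma-voom (3.39, adjusted p = 0.118).

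**Figure D1:**
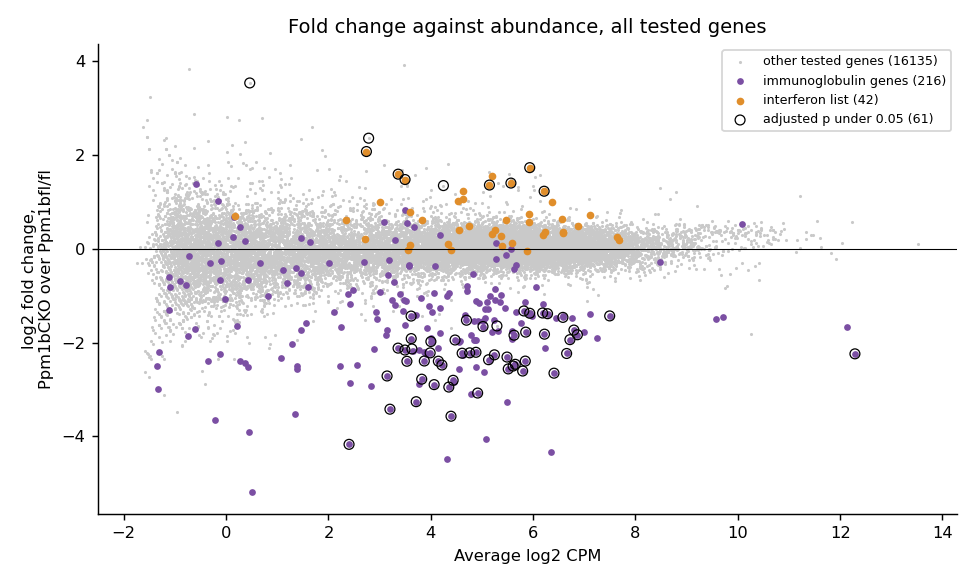
Each point is 1 of 16393 tested genes, with its average log2 CPM on the x axis and its log2 fold change, Ppm1bCKO over Ppm1bfl/fl, on the y axis; purple points are 216 immunoglobulin genes, orange points the 42 tested genes of the interferon list, and black rings the 61 genes with an edgeR adjusted p under 0.05. Ringed immunoglobulin genes lie below 0, and 39 of the 42 interferon genes lie above it.

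Immunoglobulin transcripts, which in marrow are abundant in plasma cells, made up 3.37% of counts (95% Wilson interval 3.36 to 3.38) and 2.14% (2.13 to 2.14) in the Ppm1bfl/fl libraries. In the libraries labelled Ppm1bCKO they made up 0.823% (0.819 to 0.826) and 0.975% (0.971 to 0.979). The mean share was 3.07-fold higher in Ppm1bfl/fl, 2.76% ± 0.87 against 0.899% ± 0.108 (SD, n = 2). A two-sided exact permutation test of 2 against 2 libraries cannot go below p = 0.333. Of 216 tested immunoglobulin genes, 199 had a negative log2 fold change. Because variable and constant entries can be parts of the same transcripts, this number and those by class do not count independent changes. Among 98 heavy-chain variable segments 30 fell, with a median 3.58-fold lower level over the class. Of 92 kappa and 3 lambda variable segments, 17 and 1 fell, and 1 of 12 constant genes did. That gene was Igha, the constant region of IgA (chromosome 12, 113254830 to 113260236), chosen after its values were seen. Igha went from 8261 ± 2877 to 1748 ± 170 CPM (SD, n = 2), a log2 fold change of -2.24 ± 0.30 (edgeR adjusted p = 0.0225). Without Ppm1bCKO replicate 1 its log2 fold change was -2.15 (edgeR adjusted p = 0.264), and without replicate 2 it was -2.34 (edgeR adjusted p = 0.999). Ighm, the constant region of IgM, also chosen after its values were seen, was not lower (0.53 ± 0.32, edgeR adjusted p = 0.717). The lower genes outside this family were the calcium channel gene Cacna1h (4.40-fold, edgeR adjusted p = 0.0461) and the clone AC102496.1 (3.13-fold, edgeR adjusted p = 0.0179), the latter chosen after its values were seen. The call of Cacna1h, at a log2 fold change of -2.14, was lost without Ppm1bCKO replicate 2 (-1.84, edgeR adjusted p = 0.341), with the CPM minimum (-2.14, edgeR adjusted p = 0.0596) and by limma-voom (-2.12, adjusted p = 0.0685). The genes with the next smallest p that were lower, Jchain, Axl, Camk2b, Mrc1 and Gpd1, did not pass, with edgeR adjusted p from 0.0638 to 0.117.

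**Figure D2:**
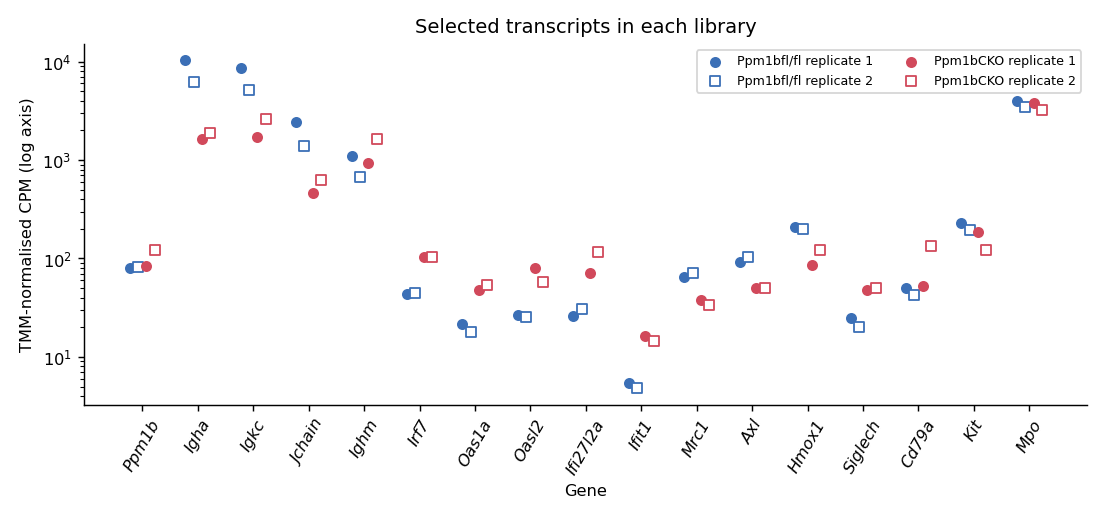
Each point is the TMM-normalised CPM of a gene in 1 library on a log axis; blue marks are Ppm1bfl/fl, red marks are Ppm1bCKO, filled circles replicate 1 and open squares replicate 2. Igha lies at 6227 and 10296 CPM in Ppm1bfl/fl and at 1628 and 1868 CPM in Ppm1bCKO, whereas Irf7 lies at 44.1 and 45.1 against 105 and 103 CPM.

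Markers of other blood cell types had medians in both directions. Of 609 genes in the other 26 fixed lists and outside the interferon list, edgeR and limma-voom called 0 over all genes and DESeq2 22, and 76 had an unadjusted p under 0.05 in edgeR. All 15 macrophage markers had a negative log2 fold change, with a median 1.55-fold lower level (camera adjusted p = 8.4e-14; adjusted p = 0.443 with an estimated correlation). Of these, 0 fell over all genes in edgeR (5 by DESeq2) and 9 fell when adjusted over the list alone. They included the receptor tyrosine kinase genes Axl (97.9 ± 7.3 to 50.3 ± 0.24 CPM; SD, n = 2) and Mertk (-1.23 ± 0.24), the mannose receptor gene Mrc1 (-0.92 ± 0.17) and the haem oxygenase gene Hmox1 (-0.98 ± 0.20). Of 16 dendritic cell markers, 13 had a positive log2 fold change (median 1.44-fold, camera adjusted p = 1.1e-06, or 0.443 with an estimated correlation). Over all genes 0 of them rose in edgeR (DESeq2 called 4), and 6 rose when adjusted over the list alone. Siglech, a surface lectin of plasmacytoid dendritic cells, stood at 22.4 ± 3.5 and 48.9 ± 2.1 CPM (SD, n = 2). The list of B cell and plasma cell markers split, and camera did not call it (adjusted p = 0.191). Over all genes 0 of its 20 members changed in edgeR (7 by DESeq2). Adjusted over the list alone 7 rose, among them the B cell surface genes Fcmr and Ms4a1. By the same adjustment 3 fell, among them Igkc and Jchain, which encodes the chain that joins IgA and IgM units. Ms4a1 had a log2 fold change of 1.71 ± 0.38 and Jchain one of -1.82 ± 0.30. This list was called higher without Ppm1bfl/fl replicate 1 (median 0.36), without Ppm1bCKO replicate 1 (0.40) and with immunoglobulin genes left out (0.22).

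Of the remaining cell type lists, 1 was called. Stromal and endothelial markers were higher (12 of 20 positive, median 1.10-fold, camera adjusted p = 0.0318; adjusted p = 0.761 with an estimated correlation), with 0 members changed over all genes or adjusted over the list alone, and the call was lost without Ppm1bCKO replicate 1 (median 0.23). Bglap, which encodes osteocalcin of bone, had a log2 fold change of 1.65 ± 0.39. Among T and NK cell markers 0 of 20 changed over all genes and the granzyme gene Gzma alone rose when adjusted over the list alone (1.32 ± 0.28), and camera did not call the list (adjusted p = 0.113), although it did without Ppm1bfl/fl replicate 1 (median 0.30). Mature neutrophil markers (17 tested, camera adjusted p = 0.204), erythroid cell markers (15 tested, camera adjusted p = 0.334) and mast cell and basophil markers (10 tested, camera adjusted p = 0.814) were not called, and 0 of their members changed over all genes or adjusted over the list alone. The mast cell list had a median of -0.04, a mean of 0.04 and a test direction of higher. The erythroid list was called in opposite directions without each Ppm1bfl/fl library, with a median of -0.19 without replicate 1 and 0.57 without replicate 2. The haemoglobin gene Hbb-bs stood at 2783 and 5049 CPM in Ppm1bfl/fl and at 4476 and 7038 CPM in the libraries labelled Ppm1bCKO.

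For the Wnt/β-catenin pathway named in the series title, target genes were not called as a list. Of 20 tested targets, 11 had a positive and 9 a negative log2 fold change, and 0 changed over all genes or adjusted over the list alone (camera adjusted p = 0.523, median 1.17-fold, or -0.15 on the log2 scale without Ppm1bCKO replicate 1). Lef1, a transcription factor that partners β-catenin and is itself a target, had a log2 fold change of 0.69 ± 0.23 (edgeR adjusted p = 0.645). Axin2, a negative feedback regulator of the pathway, had one of -0.67 ± 0.27 (edgeR adjusted p = 0.717), with Znrf3 at -0.56 ± 0.22 and Ccnd1 at -0.51 ± 0.22. Ctnnb1, which encodes β-catenin, stood at 234 ± 6.9 and 217 ± 12 CPM (SD, n = 2), and Myc, Tcf7 and Cd44 had log2 fold changes of -0.21, -0.20 and 0.25. Wnt pathway components were lower as a list by camera (27 of 32 negative, median 1.18-fold lower, adjusted p = 0.0071; adjusted p = 0.761 with an estimated correlation), with 0 changed over all genes or adjusted over the list alone. The receptor gene Fzd1 had a log2 fold change of -1.02 ± 0.39 and the co-receptor gene Lrp5 one of -0.58 ± 0.26. The call on components was lost without Ppm1bCKO replicate 2 (median -0.08) and after each library's trend with gene length was removed (-0.12), an alternative chosen after the data were seen.

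Stem cell genes were not called as a list, and lymphoid-primed genes were. Of 40 HSC genes, 27 had a negative log2 fold change and 0 changed over all genes or adjusted over the list alone (camera adjusted p = 0.419, median -0.13), although the list was called lower without Ppm1bfl/fl replicate 2 (median -0.34). Hlf, a transcription factor of HSCs, stood at 11.9 ± 5.1 and 9.74 ± 2.58 CPM (SD, n = 2). Procr, which encodes the HSC surface receptor EPCR, lay at 1.13 to 1.99 CPM and Mecom at 0.86 to 3.12 CPM over the 4 libraries. Kit, the receptor that defines the sorted fraction, ran from 121 to 228 CPM (-0.46 ± 0.22, edgeR adjusted p = 0.717). Ly6a, which encodes Sca-1 and was chosen after its values were seen, ran from 17.7 to 22.2 CPM. Immunoglobulin and haemoglobin transcripts were more abundant, with Igha at 1628 to 10296 CPM and Hbb-bs at 2783 to 7038 CPM. The eosinophil granule gene Prg2, chosen after its values were seen, ran from 1484 to 4200 CPM. Transcripts of mature blood cells at these levels argue against RNA from Lsk cells alone. The list results therefore describe all the cells collected. Granulocyte-monocyte genes (30 tested, camera adjusted p = 0.416) and megakaryocyte-erythroid genes (29 tested, camera adjusted p = 0.453) were not called, with 0 members changed over all genes or adjusted over the list alone, and the myeloid enzyme gene Mpo stood at 3736 ± 339 and 3503 ± 362 CPM (SD, n = 2). Lymphoid-primed genes were higher by camera (19 of 30 positive, median 1.16-fold, adjusted p = 9.7e-05; adjusted p = 0.761 with an estimated correlation). The list median was 0.20 on the log2 scale in Ppm1bCKO replicate 1 and 0.34 in replicate 2, against the Ppm1bfl/fl libraries. Over all genes 0 of its members changed in edgeR (3 by DESeq2). Adjusted over the list alone Pax5 and Ebf1 rose, which encode transcription factors that set B cell identity (1.09 ± 0.22 and 1.40 ± 0.31). B-lineage genes, a list written after the data were seen that shares members with this one, had a median log2 fold change of 1.32. The shared members Pax5, Ebf1, Cd79a, Cd79b and Vpreb3 had log2 fold changes from 1.01 to 1.79. The rise was not common to the lymphoid-primed list, where 11 of 30 members had a negative log2 fold change. Among these was Flt3, a receptor of lymphoid-primed progenitors (-0.20 ± 0.23).

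Cell cycle lists were not called. S phase genes (35 tested, median 1.05-fold, camera adjusted p = 0.191), G2/M genes (37 tested, 1.03-fold, 0.373) and quiescence genes (28 tested, 1.07-fold, 0.193) were not called by camera and held 0 changed genes over all genes or adjusted over the list alone. S phase genes were called higher without Ppm1bfl/fl replicate 2 (median 0.16). Mki67 and Cdk1, which mark cycling cells, had log2 fold changes of -0.31 ± 0.27 and 0.32 ± 0.18. The p53 target genes were higher by camera (18 of 26 positive, median 1.11-fold, adjusted p = 0.0318; adjusted p = 0.761 with an estimated correlation), with 0 changed over all genes or adjusted over the list alone. The cell cycle inhibitor gene Cdkn1a stood at 53.1 ± 4.5 and 76.9 ± 3.3 CPM (SD, n = 2; edgeR adjusted p = 0.557). The p53 list lost its call without Ppm1bfl/fl replicate 2 (median 0.10), Ppm1bCKO replicate 1 (0.18) or Ppm1bCKO replicate 2 (0.08).

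Among stress and signalling lists, NF-kB target genes were higher by camera (24 of 35 positive, median 1.10-fold, adjusted p = 0.0038; adjusted p = 0.761 with an estimated correlation), and 0 changed over all genes or adjusted over the list alone. Nfkbia, an inhibitor and feedback target of NF-kB, had a log2 fold change of 0.73 ± 0.20. The call on the NF-kB list was lost without Ppm1bfl/fl replicate 2 (median 0.10), and its median log2 fold change ranged from 0.10 to 0.39 over the alternatives. Immediate-early and heat shock genes were not called (23 tested, camera adjusted p = 0.595), with a median of 0.06, a mean of -0.08 and a test direction of lower. Over all genes 0 of them changed, and Fos, a subunit of the AP-1 transcription factor, fell when adjusted over the list alone, from 1123 to 643 CPM on average. Without Ppm1bCKO replicate 2 that list was called lower (median -0.14). TGF-beta/BMP target genes (21 tested, camera adjusted p = 0.191), MAPK feedback genes (21 tested, 0.814) and necroptosis and apoptosis genes (26 tested, 0.191) were not called and held 0 changed genes over all genes or adjusted over the list alone. The TGF-beta/BMP list was called higher without Ppm1bfl/fl replicate 1 (median 0.28) and without Ppm1bCKO replicate 2 (0.23). Of the metabolic lists, oxidative phosphorylation genes were higher by camera (47 of 49 positive, median 1.27-fold, adjusted p = 6.9e-08; adjusted p = 0.761 with an estimated correlation), with 0 changed over all genes or adjusted over the list alone. Their median log2 difference from Ppm1bfl/fl was 0.01 in Ppm1bCKO replicate 1 and 0.60 in replicate 2, and the call was lost without replicate 2 (median 0.0049). Glycolysis genes were not called (24 tested, camera adjusted p = 0.674, median 0.0028, mean -0.09, tested lower), with 0 changed over all genes or adjusted over the list alone. With camera's correlation estimated from the data, 0 of the 27 lists were called, compared with 9 at the preset correlation (7 higher, 2 lower). The estimated version rests on the few residual degrees of freedom that 2 libraries per genotype leave, so it could call hardly any list. The preset version takes genes rather than libraries as replicates. Neither version therefore decides whether a list differs between the genotypes. The directional fry test, which asks whether the members of a list moved one way on balance, called 0. It rests on the same few residual degrees of freedom, so it does not decide the question either. Its lowest adjusted p was 0.087, for the interferon list.

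**Figure D3:**
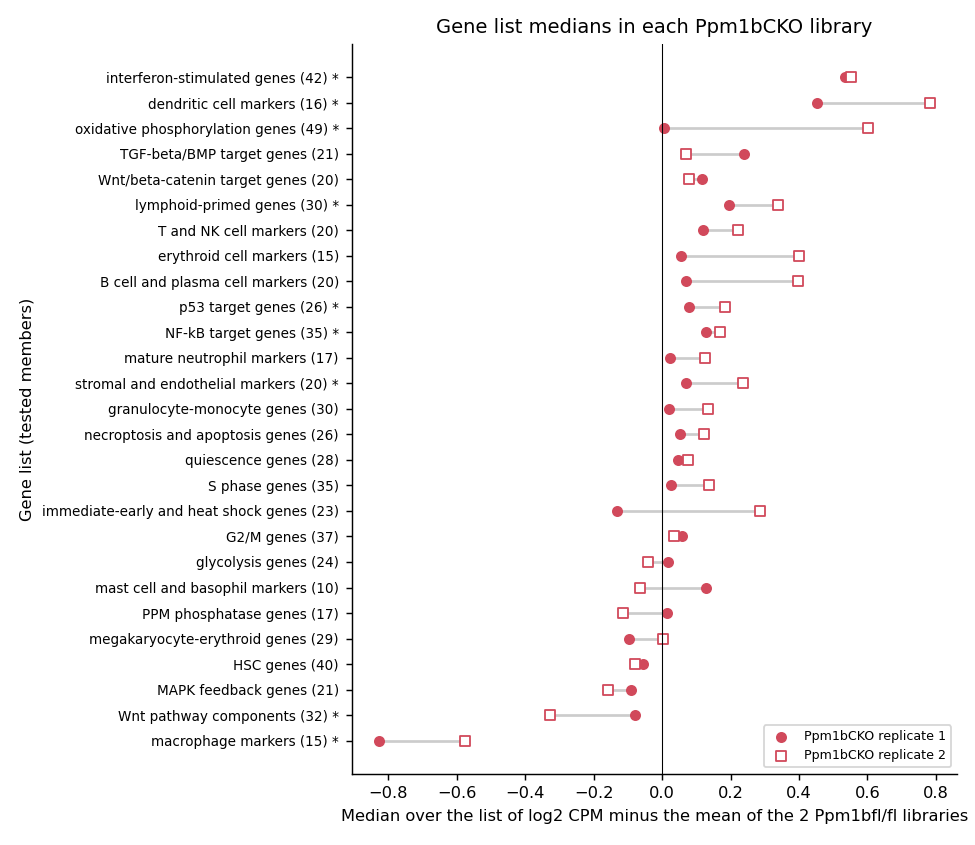
For each of 27 gene lists (tested members in brackets), points give the median over its members of log2 CPM in Ppm1bCKO replicate 1 (filled circles) or replicate 2 (open squares) minus the mean of the 2 Ppm1bfl/fl libraries; asterisks mark camera adjusted p under 0.05 at the preset correlation, 9 lists. The interferon list sits at 0.53 and 0.55, whereas the oxidative phosphorylation list sits at 0.01 and 0.60.

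Ppm1bCKO replicate 2 stood apart from the other libraries. It held 2 counts over Ddx3y, Kdm5d, Eif2s3y and Uty, genes of the Y chromosome, against 5870 to 6396 in each other library. The first principal component, 60.7% of the variance, placed it at 60.5 and the others between -32.7 and -5.8. Short genes were higher and long genes lower in it, with a median log2 deviation of 0.31 in the shortest of 4 equal groups of genes and -0.25 in the longest. Without this library 94 genes changed (31 higher, 63 lower), including 41 of the 61, and without Ppm1bCKO replicate 1 the count was 3336 (1753 higher, 1583 lower). Without Ppm1bfl/fl replicates 1 and 2 the counts were 145 and 214. Immunoglobulin genes that fell numbered 47 without Ppm1bCKO replicate 2, and interferon-list genes that rose numbered 12.

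**Figure D4:**
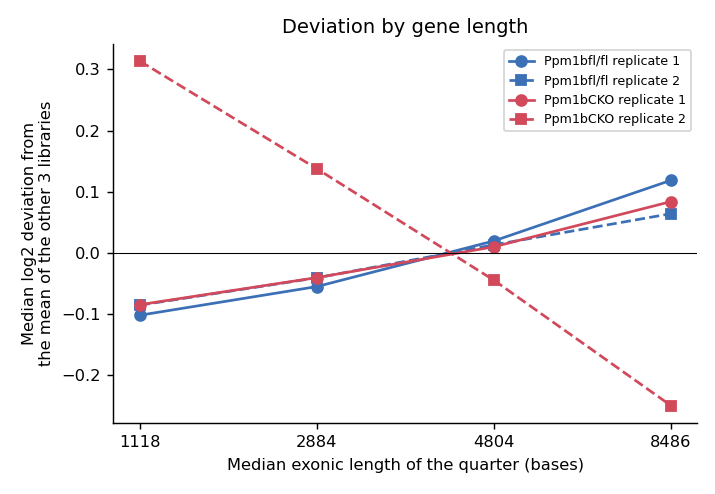
For each library, points joined by lines give the median log2 deviation from the mean of the other 3 libraries over genes in 4 groups of equal size by exonic length, at their median length in bases. Ppm1bCKO replicate 2 goes from 0.31 in the shortest group to -0.25 in the longest, and the other 3 libraries rise from -0.10, -0.09 and -0.08 to 0.12, 0.06 and 0.08. The mean that each of those 3 is set against includes Ppm1bCKO replicate 2, so their rise follows at least in part from its fall.

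Of 54 tested genes within 5 Mb of Ppm1b, edgeR called 0 (two-sided Fisher's exact p = 1), and 2 had an unadjusted p under 0.05. Only 61 of the 16339 other tested genes changed, so 0 of 54 was a likely outcome in any case. The test therefore does not exclude linked sequence around Ppm1b. No Fisher p lay below 0.511 with windows of 1 and 10 Mb, DESeq2, the replicate block, the length trend removed, or each library left out in turn.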

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

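The gene-length and immunoglobulin alternatives were chosen after the data were seen, and the others before. The counts of changed, higher, lower, immunoglobulin lower and interferon-list higher genes were 61, 10, 51, 49 and 7. They were 199, 67, 132, 108 and 12 with DESeq2, and 311, 130, 181, 124 and 14 without a low-count filter. DESeq2 size factors, limma-voom, the CPM minimum and the removed length trend gave 62, 50, 55 and 55 changed genes, with 61, 50, 55 and 45 of the 61 kept. A fold threshold of 1 on the log2 scale removed 0. With the replicate number as a block they were 207, 71, 136, 107 and 12, with 59 of the 61 kept. The numbers were not shown to pair the samples, since the labels give no shared origin and there are only 2 pairs (deviations of same-numbered samples correlated at 0.064 across genes, which are not independent replicates). The block also ended the call of the stromal list. With immunoglobulin genes left out, edgeR called 0 genes (0 higher, 0 lower, 0 of the interferon list), with 989 at an unadjusted p under 0.05. Limma-voom called 0 genes there and DESeq2 79, including all 12 of the main calls outside the family. Fold changes hardly moved (Irf7 1.22 in both fits) and its unadjusted p went from 4.4e-05 to 3.2e-05. The edgeR calls ended because the adjustment no longer included the small p-values of immunoglobulin genes. Camera with an estimated correlation and fry called 0 lists, so the interferon (median 0.59) and macrophage (-0.63) lists lost their calls at the same medians, by construction of the tests. Leaving out each library in turn (a lone library is assumed to vary like the other genotype) gave 94 to 3336 changed genes, 31 to 1753 higher, 63 to 1583 lower, 47 to 132 immunoglobulin lower and 6 to 20 interferon-list higher. The highest total came without Ppm1bCKO replicate 1, where Ppm1bCKO replicate 2 alone stands for its genotype. Ppm1b ranged from 0.046 to 0.56 (past the threshold only without Ppm1bCKO replicate 1), and the erythroid list median from -0.19 (reversed, without Ppm1bfl/fl replicate 1) to 0.57, and the cause was not tested. Of 1921 values of 161 other named genes, 1628 kept sign and side of the threshold, 25 changed sign without being called in either fit, 24 lost and 244 gained a call, and 0 changed sign with a call. Of 288 medians of 24 other lists, 239 kept both, 15 changed sign without being called in either fit, 23 lost and 10 gained a call, and 1 (erythroid) gained a call against the camera direction of the main fit. The median of 1 of the 10, the immediate-early list, turned to -0.14 without Ppm1bCKO replicate 2, where camera called it in the direction of the main fit. The Wnt target list was called under no alternative, and its median went from -0.15 (without Ppm1bCKO replicate 1) to 0.22. In simulated counts 40 of 100 genes changed 2-fold were recovered.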

Other observations

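The lists of B-lineage, eosinophil granule, plasmacytoid dendritic cell and non-immunoglobulin plasma cell genes, and the tests of gene length, sex, normalisation, plasma cells, B-lineage cells, plasmacytoid dendritic cells and Ppm1bCKO replicate 2 alone, were chosen only after the results were seen. Standard errors of list medians here are taken over genes, which are not independent replicates, and do not cover the spread between libraries. All 11 B-lineage genes had a positive log2 fold change, with a median of 1.32 ± 0.13 (SE). Over all genes edgeR and limma-voom called 0 of them, DESeq2 called 7, and 11 had an unadjusted p under 0.05 in edgeR. Vpreb3, expressed in B cell precursors, stood at 9.08 ± 1.04 CPM in Ppm1bfl/fl and 31.4 ± 24.7 CPM in the libraries labelled Ppm1bCKO (SD, n = 2). The list median was 0.70 in Ppm1bCKO replicate 1 and 1.78 in replicate 2. Of the 11 genes, 8 also belong to lists fixed in advance.

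All 6 eosinophil granule genes had a positive log2 fold change, with a median of 1.09 ± 0.15 (SE), and edgeR and limma-voom called 0 of them over all genes, DESeq2 called 5, and 5 had an unadjusted p under 0.05 in edgeR. Prg2, the major basic protein of eosinophil granules, stood at 1486 ± 2.4 and 3243 ± 1353 CPM (SD, n = 2) and was the fifth most abundant gene of Ppm1bCKO replicate 2, at 0.401% of its counts. The eosinophil-associated ribonuclease genes Ear1, Ear2 and Ear6, paralogs whose reads may be shared, had log2 fold changes of 1.28, 1.20 and 1.06. The list median was 0.59 in Ppm1bCKO replicate 1 and 1.47 in replicate 2. Apart from Epx these genes are short, with exonic lengths of 719 to 949 bases, and short genes were higher in Ppm1bCKO replicate 2. Epx, at 2737 bases, had a log2 fold change of 0.45 ± 0.21. All 6 genes kept a positive log2 fold change under every alternative, including the fit with each library's length trend removed. Their lowest values over the alternatives ran from 0.247 for Epx to 0.621 for Prg2. These ranges do not give how much of the rise goes with gene length.

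Ppm1bCKO replicate 2 lay apart from the other libraries on the first principal component. GC content is argued against, because with length held the partial Spearman rho across genes between GC and the deviation of this library was -0.0373, although it reached -0.177 in Ppm1bCKO replicate 1. Recovery that depends on gene length stays open, since the Spearman rho across genes between exonic length and deviation was -0.336, against 0.148 to 0.222 in the others. The positive values in the others follow at least in part from the method, because the mean they are set against includes this library. The sex of the mouse cannot be told apart from the library, because it is the only library with as few as 2 Y-linked counts, and without X- and Y-linked genes the component still held 59.8% of the variance with this library at one end. Genes are not independent replicates in these correlations.

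Lower immunoglobulin transcripts in the libraries labelled Ppm1bCKO could reflect a shift in normalisation or in the cells collected. Normalisation is argued against by the ratio of immunoglobulin to other counts within a library, which no scale factor enters. That ratio was at least 2.22-fold higher in each Ppm1bfl/fl library than in each library labelled Ppm1bCKO. For fewer B-lineage cells of every stage no verdict is drawn, because that list and its bound were written after the values were seen. The B-lineage median was 1.32, with 0.70 in Ppm1bCKO replicate 1 and 1.78 in replicate 2, and edgeR called 0 of the 11 genes. Fewer plasma cells among the collected cells, whether from the sort or the genotype, stay open. The median of 10 plasma cell genes other than immunoglobulin was -0.532 ± 0.288 (SE), which passed the bound of -0.5 by less than its error. This median was -0.73 in Ppm1bCKO replicate 1 and -0.41, short of the bound, in replicate 2. Of the 10 genes, 2 are also in fixed lists, and Jchain was at -1.82 and Derl3 at -1.32 but Creld2, Fkbp11 and Sdf2l1 above 0. Igha and Igkc, at up to 10296 and 8609 CPM, were the most abundant transcripts of that kind, and selection for lineage-negative cells would be expected to remove many B cells.

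Higher interferon-stimulated genes may reflect an interferon response that goes with the genotype, which was not tested apart, more plasmacytoid dendritic cells, or the library that stood apart. The gene-length trend as the whole cause is argued against, because the list median stayed at 0.509 after the trend was removed, with 8 members past the threshold, and so is Ppm1bCKO replicate 2 alone, because the median was 0.534 in replicate 1. Plasmacytoid dendritic cells, many of which selection for lineage-negative cells would be expected to remove, cannot be told apart from a response, since the median of the 42 interferon list members minus that of 6 plasmacytoid genes was -0.483 ± 0.385 (SE), within 2 standard errors of 0. All 6 plasmacytoid genes, 4 of them also in fixed lists, had a positive log2 fold change, with a median of 1.07 ± 0.37 (SE) and Siglech at 1.12, and edgeR called 0 of them. The 4 libraries form 3 splits into 2 and 2, too few for a share under 0.05: the real split gave 61 changed genes, as 1 of 3, and the highest other gave 0.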
